A study of Homo sapiens with 4 samples.

How the data were processed

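RNA of HL-60 cells, an established human promyelocytic leukaemia line, was compared on arrays of long oligonucleotides between cultures given 12.5 nM bufalin and cultures given the solvent DMSO for 6, 12, 24 or 48 h. Each of the 4 time points was hybridised on 2 arrays with the dyes exchanged, 8 arrays in all. The 2 arrays of a time point hold the same RNA, so they are technical repeats, and each time point has 1 bufalin culture and its own DMSO culture. The arrays made with unexposed cells were not analysed here.

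Per the file headers, the scanner files give for each spot the foreground, the local background and the background-subtracted intensity of Cy5 and Cy3. The deposited ratio of each array was Cy3 over Cy5 on the first array of a pair and Cy5 over Cy3 on the swapped one, after a normalization that depends on intensity and whose method is not stated. This reading was taken from the values, by setting the ratio against the 2 intensities. Per the file headers, a score gives the percent of a spot's pixels above background by 2 SD in each dye. The deposited value table holds 1 log2 ratio per probe and time point for 21329 probes. Among expressed probes it equalled the mean of the 2 arrays to within 0.02 for 93.0% at 6 h, 61.2% at 12 h, 85.3% at 24 h and 94.6% at 48 h. Of the 55, 377, 122 and 46 probes that differed, 53, 91, 72 and 45 equalled 1 of the 2 arrays.

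The scanner files used here hold only the first blocks of each array, between 8.20% and 14.7% of the probes (1749 to 3124 spots). Between 3.59% and 4.26% of their lines were left out. These were damaged lines, lines without an oligo name of the expected form or a ratio above 0, and repeats of an oligo, not counted apart. Median intensity per array ran from 129 to 424 in Cy5 and from 301.5 to 939 in Cy3, and at most 5 spots per dye and array were saturated. The number of arrays limits the precision. Of 3222 oligos read, 2042 were named through an accession, 353 through a symbol and 241 through a synonym, 339 kept the name of the array, and 247 had none. Genomic positions were not used here, and 18107 probes of the value table lie outside the scanner files and had no name.

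The deposited ratio was taken as log2, each array was centred on the median of its expressed probes, and the 2 arrays of a time point were averaged. A probe was expressed at a time point when at least 1 of its 4 intensities exceeded 800, and, where both intensities of an array were under 800, one of the other array exceeded 3000 before it could be called. An RNA was dim when, on both arrays, fewer than 50% of its pixels were above background or its signal was not above 0. A fold with a dim RNA was given only as a lower bound ("at least"), with that RNA set to the level of the lowest probe above background after loess and Aquantile normalization. No fold was given where both RNAs were dim or the bound was under 1. Over the 4 time points the bound was used where an RNA was dim on all 8 arrays and the other on fewer than 4, and otherwise neither a fold nor a log2 mean was given where it was dim on 4 or more. For the chemokine list alone, medians are given also with values that have a dim RNA at their bound, or at 0 where there was none.

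Over the 4 time points, limma 3.58.1 (R 4.3.3) tested the mean log2 ratio of each probe against 0, and in a second fit its slope on log2 hours, with 1 value per time point. The 646 probes with values on all 8 arrays and expressed at 2 or more time points were tested. The p-values were two-sided and adjusted by Benjamini-Hochberg at 0.05, and the prior had 7.23 degrees of freedom. A test over time points asks whether a gene stayed on one side of 0, and cannot call a gene that moved at a single time. At single time points no test was possible. A size rule was applied there, at least 1.5-fold at 6 h and 2-fold at the later times, with both arrays on the same side of 0.

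Before the data were examined, 39 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 5 tested members went into limma's camera with a preset correlation of 0.01, and again with an estimated correlation and with fry, both for one direction and for either. Per time point, a list's median was set against 10000 random lists of the same size matched on intensity. Named over the 4 time points were up to 15 genes per side past the threshold, per time point the 12 highest and 12 lowest that met the size rule, and for the slope the 5 smallest p if none passed. List members could always be named. Probes without a name, Y-linked genes, XIST and a few further genes were left out of the naming but not out of the counts and tests. No named gene had a further probe with a value in the scanner files.

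Tested on 50 simulated data sets with 200 of 646 probes changed, the mean fit recovered 85.1% of changes of 1 and 98.3% of changes of 2 on the log2 scale, with 3.57% false calls. Each simulated change of the mean was the same at all 4 times, so recovery may be lower where fewer probes change or changes vary with time. The slope fit recovered 30.9% of slopes of 0.5 and 83.2% of slopes of 1 per doubling of time, with 2.92% false calls. The simulated noise was normal, unrelated to intensity and, for a probe, equally wide at all 4 times. In the data the SD of the log2 ratios of expressed probes ran from 0.57 at 6 h to 0.83 at 48 h. The shares of false calls may therefore be higher in the data. Camera called a list of 6 genes shifted by 1 in 100% of the simulations and gave a p under 0.05 for 4.10% of unshifted lists. The simulated genes were independent of one another, so these rates do not cover lists whose members move together. The chemokine list called below had an estimated correlation of 0.544. Alternatives covered normalization, intensity filters, offsets, background correction, single arrays, single time points left out, the value table, the prior, and the list test. With loess alone, with 200 added to both intensities, and with normexp, the deposited ratio was replaced. It was computed anew from the intensities, with loess within each array. With loess alone, spots with an intensity not above 0 were dropped. Parsing and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.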

Results

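The arrays compared mRNA levels in HL-60 cells given bufalin, a steroid of toad venom, with levels in time-matched cells given solvent, to follow the response from 6 to 48 h. There were 4 time points with 1 bufalin and 1 DMSO culture each, and 2 dye-swapped arrays per time point. No time point had a biological replicate, so spreads at single times are between repeat arrays of the same RNA. Both arrays of a pair gave values for 2329, 1699, 1834 and 1895 probes at 6, 12, 24 and 48 h, of which 794, 1011, 843 and 895 were expressed.

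The deposited ratio ran the same way on all 8 arrays, but which RNA is its numerator was not settled. The sample titles name bufalin before DMSO, and on that reading a positive log2 ratio means more RNA with bufalin. The dye labels, read in the order of the arrays, give the opposite reading, on which a positive ratio means more RNA with DMSO. All values are therefore given as lying on the positive or the negative side of the deposited ratio, and the sizes hold on either reading. Across the expressed probes of a time point, which are not independent replicates, Pearson's r between the paired arrays was 0.46 at 6 h, 0.07 at 12 h, 0.57 at 24 h and 0.34 at 48 h. Spearman's rho was 0.22, 0.09, 0.63 and 0.54.

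**Figure D1:**
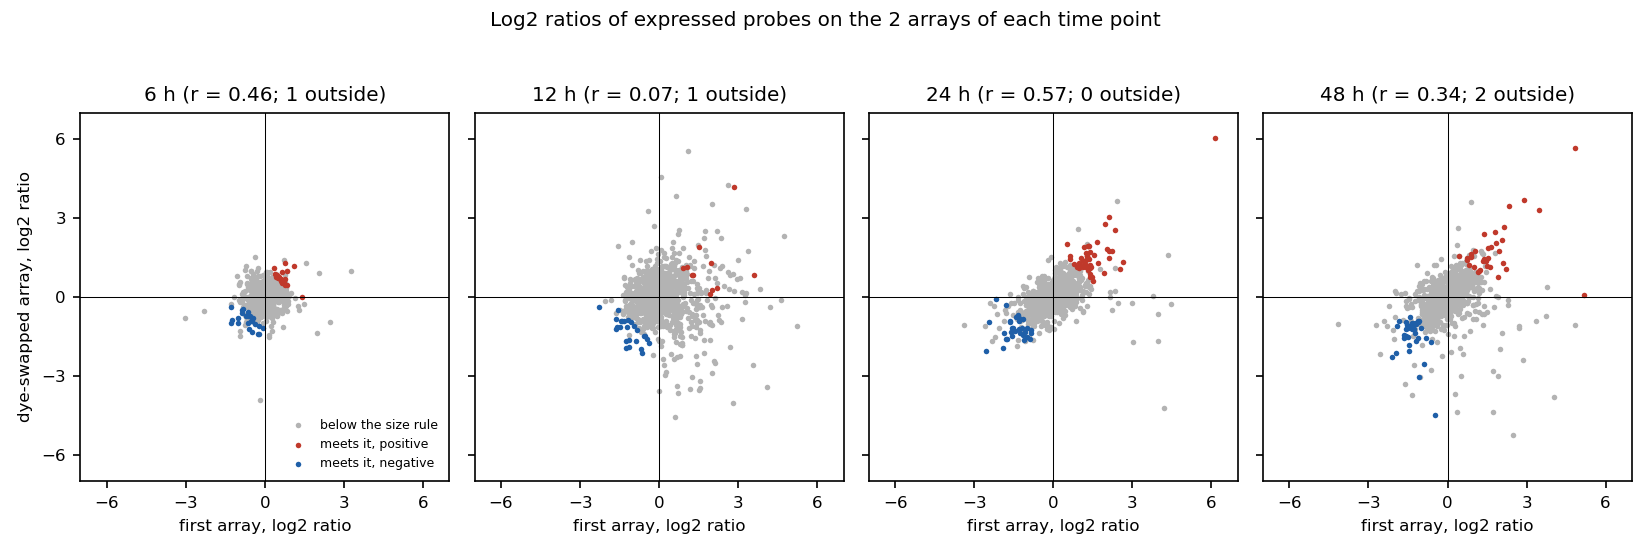
Log2 ratio of each expressed probe on the first array (x axis) against the dye-swapped array (y axis) at 6, 12, 24 and 48 h, with probes that met the size rule in red (positive) or blue (negative). The pairs at 24 and 48 h lie along the diagonal more than the pair at 12 h, with Spearman's rho of 0.63 and 0.54 against 0.09, and 1, 1, 0 and 2 probes fall outside the axes.

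Over the 4 time points, CXCL8, the neutrophil-attracting chemokine interleukin-8, lay on the positive side by at least 5.32-fold (n = 4 time points, limma adjusted p = 0.0044), a lower bound because its weaker RNA was not above background on any of the 8 arrays. CCND3, the G1 cyclin D3, lay on the positive side with a mean log2 ratio of 1.66 (SE 0.21, limma adjusted p = 0.0044), a 3.16-fold difference with both RNAs above background on all 8 arrays. On the negative side was NR1D2, a nuclear receptor of the circadian clock, at −1.06 (SE 0.20, limma adjusted p = 0.0360, 2.09-fold). All 3 genes kept their side at all 4 time points.

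In all, 15 of 646 probes passed the threshold (10 positive, 5 negative), and 125 had an unadjusted p under 0.05 where 32.3 would be expected by chance. C1orf56 lay on the positive side at 1.15 (SE 0.24, 2.22-fold) and YRDC, a tRNA-modifying enzyme, at 0.91 (SE 0.19, 1.88-fold). C5AR1, the receptor for complement C5a, RELB, an NF-kappaB subunit, PLEKHO2 and the activation marker CD69 also passed on the positive side, and CDKN2C, an inhibitor of the cyclin D kinases, on the negative side. For these 5 genes an RNA was not above background on 4 to 7 of the 8 arrays, so no size is given. At 12 h the deposited value table has C5AR1 on the opposite side (−0.65). The adjusted p of these 7 genes, C1orf56 and YRDC included, ran from 0.0361 to 0.0496.

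Of the remaining named genes, 3 were dim throughout. SIGIRR, a receptor that dampens interleukin-1 signalling (limma adjusted p = 0.0219), and KIAA1196 (limma adjusted p = 0.0402) passed on the negative side, each with an RNA dim on all 8 arrays and the other on 6, so no fold is given. DPP4, a cell-surface peptidase, passed on the positive side (limma adjusted p = 0.0219), but both its RNAs were below background on all 8 arrays and its paired arrays lay on opposite sides of 0 at 6, 12 and 24 h. The call count depended on single samples, with 0 probes without 48 h, 3 without 24 h, 8 without 12 h and 43 without 6 h. It was 2 with the first arrays alone, 1 with the swapped arrays alone, 0 with no intensity filter, and 29 of 285 among probes with both RNAs above background at every time, and in the value table of the same probes 7 passed on the positive and 13 on the negative side.

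**Figure D2:**
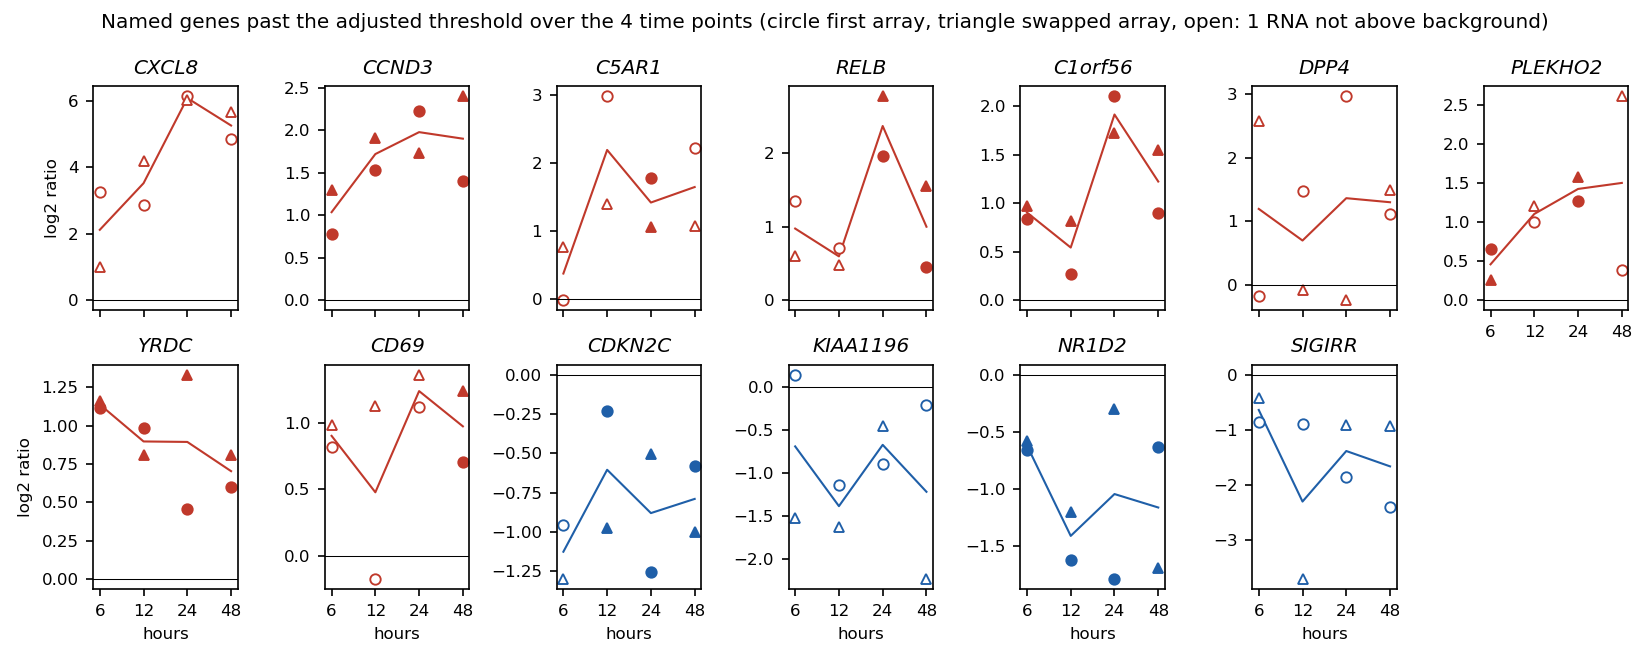
Log2 ratio (y axis, scaled separately for each gene) against hours of exposure for the 13 named genes past the threshold over the 4 time points, with the first array as a circle, the swapped array as a triangle, their mean as a line, and open symbols where an RNA was not above background. The means of CCND3 run from 1.04 at 6 h to 1.98 at 24 h, and those of NR1D2 from −0.62 at 6 h to −1.41 at 12 h.

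Of the 39 fixed lists, 3 had enough tested members for a test, and the chemokines, cytokines and NF-kappaB targets were the one called. All 6 tested members (CXCL8, CCL3, CD83, RELB, NFKB2 and NFKB1) lay on the positive side, with a mean of 1.56 and a median of 1.15 (camera adjusted p = 3.32e-06), or 1.08 and 0.95 with values that have a dim RNA set to their bound. With an estimated correlation the call was lost (adjusted p = 0.237), as it was with fry (adjusted p = 0.144), while fry for members that move in either direction gave an adjusted p of 0.0454. Over all genes tested 2 members passed, CXCL8 and RELB, and adjusted over the list alone 5 did. NFKB1, at a mean of 0.48, came to −0.03 with the first arrays alone.

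The promyelocyte granule and progenitor genes were not called, with 3 of 6 tested members above 0 and a mean of −0.04 (camera adjusted p = 0.996, and 0.941 with fry in either direction). That mean turned positive, to 0.10, with the first arrays alone, and to 0.02 without 24 h and 0.07 without 48 h. The G1/S and DNA replication genes were not called either, with 2 of 7 above 0, a mean of 0.07 carried by CCND3 and a median of −0.16 (camera adjusted p = 0.996). Their mean came to −0.002 with the first arrays alone, and fry for members that move in either direction gave an adjusted p of 0.0142. Adjusted over the list alone, CCND3 passed on the positive side and 1 member on the negative side.

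With 4 tested members the cholesterol synthesis genes were too few for the list test. Of these 2 lay above 0 and 1 passed over all genes on the negative side, or 2 adjusted over the list alone. IDI1, an isomerase of this pathway, had a mean of −0.84 and missed the threshold over all genes (SE 0.20, limma adjusted p = 0.0529).

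**Figure D3:**
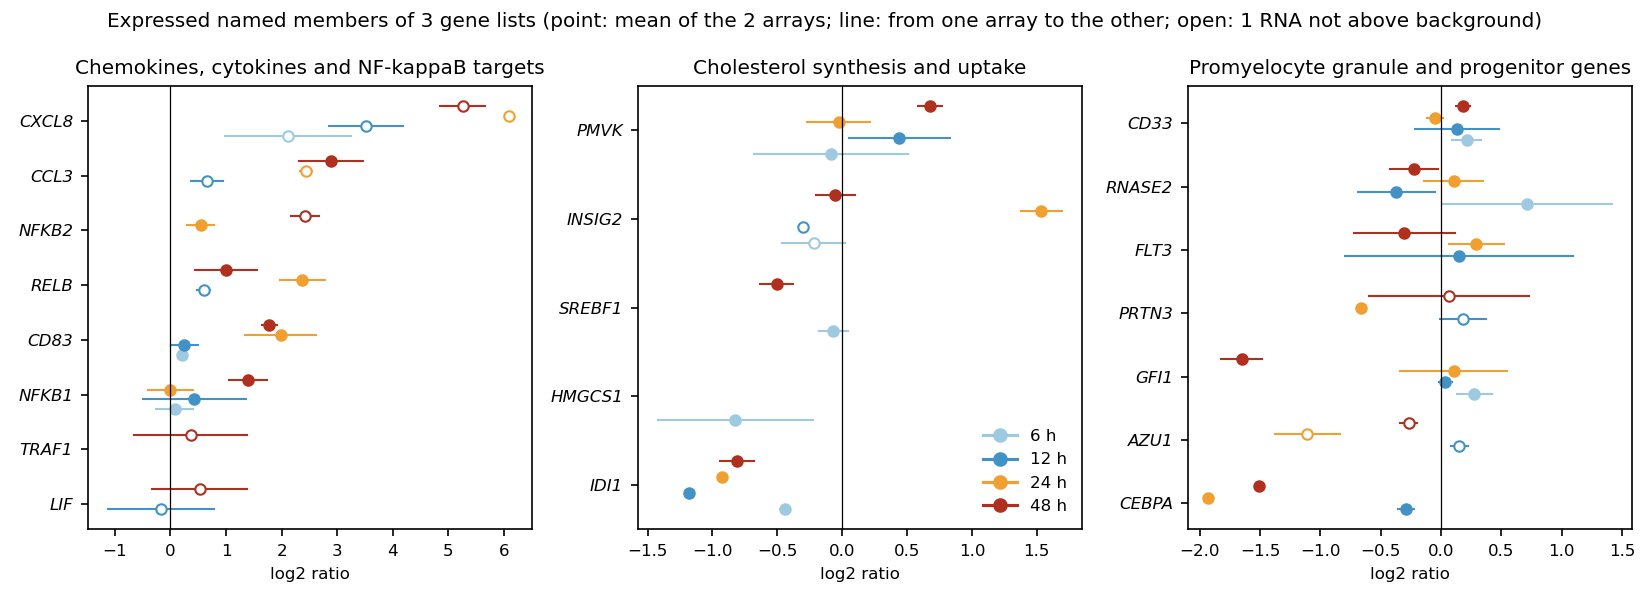
Log2 ratios (x axis, scaled separately for each list) of the expressed named members of 3 gene lists (y axis) at each time point, as the mean of the 2 arrays with a line from one array to the other, open where an RNA was not above background. CD83 and RELB lie between 1.00 and 2.37 at 24 and 48 h, while IDI1 lies between −0.44 and −1.18 at all 4 times.

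A second test asked which genes moved steadily with time. The CDK inhibitor CDKN2B lay at 0.86 at 12 h, 1.79 at 24 h and 3.38 at 48 h, and was below background at 6 h. Its slope, which rests in part on that 6 h value, was 1.14 per doubling of time (SE 0.17) and did not pass (limma adjusted p = 0.0931). Next came CCL3 (limma adjusted p = 0.106), with an RNA below background at 6, 12 and 24 h, and CRIM1 and TFDP2 (limma adjusted p = 0.326 for both) and CXCL8 (limma adjusted p = 0.347), with one below background at all 4 times, so no slope is given for these. With limma 0 of 646 probes passed, and 39 had an unadjusted p under 0.05 where 32.3 would be expected. Without 24 h 8 probes passed and without 12 h 5, CDKN2B and CCL3 among them each time.

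At 6 h the size rule asked which genes differed early. YRDC (log2 ratio 1.14, SD between arrays 0.03), CCND3 (1.04, SD 0.37), C1orf56 (0.91, SD 0.09) and the homeobox gene PITX1 (0.81, SD 0.22) were farthest on the positive side. RNF135, a ubiquitin ligase, lay at −1.15 (SD 0.22), KBTBD11 at −1.06 (SD 0.27) and NGLY1, which removes sugar chains from misfolded proteins, at 2.01-fold to the same side (SD 0.002). All 6 expressed cholesterol genes were below 0, with a median of −0.33 at percentile 1.29 of random lists and a dim RNA for INSIG2. On the negative side 2 met the rule, among them HMGCS1, an early enzyme of the pathway, at −0.82 (SD 0.84).

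Other genes that met the rule at 6 h on the positive side were CLK3, SLC25A17, RNASE2, DUSP23, PRKRA, SMYD5 and ARPC1B, between 0.63 and 0.73, and the proteasome subunit PSMB5, at least 1.41-fold. RNASE2 lay at 1.42 on the first array but at 0.009 on the swapped one (SD 0.99). On the negative side were LOC199692, THUMPD3, ICE1, ZNF23, DDX20 and MIOS, between −0.93 and −0.74, RHOU at least 1.6-fold, and PRTFDC1, with no fold because its RNA was dim. Of the chaperones, HSP90AB1 met the rule at −0.71, and PRIM1, a DNA primase, at −0.68. In all 44 probes met the rule (20 positive, 24 negative), and 24 did so when the sign of the swapped array was turned, which leaves only dye and spot effects. At 2-fold the count was 6. With 200 added to both intensities before loess it was 14, against 26 with loess alone.

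At 12 h CXCL8 was at least 1.83-fold to the positive side, and CCND3 lay at 1.72 (SD 0.27). The histone gene H4C3 (1.10, SD 0.07), the stress-induced factor ATF3 (1.06, SD 0.31), FLJ20060 (1.03) and BUD13 (1.01) also met the rule. On the negative side were EPDR1 (−1.58), NR1D2 (−1.41, SD 0.30), the heat shock protein HSPH1 (−1.32, SD 0.23), the dynein light chain DYNLL1 (−1.27) and NGLY1 (−1.24). IDI1 met the rule at −1.18 (SD 0.04).

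The chemokine and NF-kappaB list had a median of 0.51 at 12 h, at percentile 97.1, with 5 of 6 members above 0 and CXCL8 alone meeting the rule. An RNA was dim for 4 of the 6 (CXCL8, RELB, CCL3 and LIF), the median was 0.12 with these at their bound, and the deposited value table has RELB (−0.20) and CCL3 (−0.90) on the negative side. Genes with a dim RNA were MRS2, MRPL24 and CSTB, at least 2.00-fold to the negative side, THRA, ATRAID and KIAA1196, at least 1.10-fold, and ALPI, at least 1.36-fold to the positive side. PSCA, PRUNE2, FAM3B and ATP7A met the rule with no fold that could be bounded. In all 36 probes met it (11 positive, 25 negative), 19 with both RNAs above background, against 7 with the swapped sign turned. Over all expressed probes the paired arrays were least alike at this time. Among probes with all 4 intensities above 800 those at 6 h were less alike (Pearson's r 0.21 against 0.44). At 12 h 12 probes passed 2-fold on each array, and in the value table of the same probes the split was 25 positive and 23 negative.

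At 24 h the chemokine and NF-kappaB genes stood out, with a median of 2.18 over 6 expressed members, above all 10000 random lists (percentile 100), and of 1.71 with its 2 dim members at their bound. CXCL8 was at least 14.9-fold and CCL3 at least 2.70-fold to the positive side. RELB lay at 2.37 (SD 0.57) and CD83, a marker of activated dendritic cells, at 1.98 (SD 0.91), while NFKB2 was at 0.54 and NFKB1 at −0.003. Also positive were TRA, the T cell receptor alpha locus (2.58, SD 0.63), CCND3 (1.98), FLJ22794 (1.93), C1orf56 (1.92), the transcription factor BATF3 (1.87), the phosphatase PTPRE (1.80), CDKN2B (1.79) and BIN2 (1.65).

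On the negative side at 24 h were ACAT1, a mitochondrial thiolase (−2.31, SD 0.37), CEBPA, a transcription factor of granulocyte development (−1.93, SD 0.01), and the chaperone HSP90AB1 (−1.71, SD 1.05). They were followed by MRPL24 (−1.70), SND1 (−1.68), the DNA repair enzyme APEX1 (−1.62), BLMH (−1.47), GAL (−1.39), the translation factor EIF5B (−1.37) and CAT, the catalase (−1.35). GCA was at least 2.70-fold and MEST at least 2.29-fold to the same side. Of 8 expressed G1/S genes 2 were above 0 (median −0.36, percentile 5.59), with TYMS at −1.04 and UNG at −1.01 against CCND3. At 6, 12 and 48 h the G1/S list lay at percentiles 48.2, 71.5 and 63.3. Among other lists, HSP90B1, a chaperone of the endoplasmic reticulum, met the rule at −1.31, and INSIG2 (1.53) and CEBPG (1.48) did on the positive side. In all 81 probes met the rule (50 positive, 31 negative), against 0 with the swapped sign turned. With all 4 intensities above 800 the count was 39 and the share of positive probes went from 61.7% to 38.5%. With 200 added to both intensities before loess the count was 41, against 62 with loess alone.

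At 48 h CXCL8 was at least 24.9-fold and NFKB2 at least 3.65-fold to the positive side, with CCL3 at 2.89 (SD 0.81), CD83 at 1.78 (SD 0.19), NFKB1 at 1.40 (SD 0.48) and RELB at 1.00 (SD 0.78). All 8 expressed members of their list were above 0 (median 1.59, also with the dim ones at their bound, percentile 100), and 6 met the rule. CDKN2B lay at 3.38 (SD 0.14), TRA at 3.29 (SD 0.53), PTPRE at 1.96, CCND3 at 1.90, the spindle protein SPAG5 at 1.85, and ATP11A and CHRNB4 at 1.70. RAB5C was at least 3.11-fold, but its arrays lay far apart (SD 3.62).

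On the negative side at 48 h were QARS1, the glutaminyl-tRNA synthetase (−2.19, SD 0.13), GFI1, a repressor needed for neutrophil development (−1.65, SD 0.24), and STAT2, a factor of interferon signalling (−1.54, SD 0.14). CEBPA (−1.51, SD 0.01), the tRNA synthetase FARSA (−1.29), HSP90AB1 (−1.22), PRIM1 (−1.18) and the ribosome assembly factor WDR12 (−1.03) also met the rule. With a dim RNA, DKFZP586M1523, PHKA2, MEST, KBTBD11, PTGER2, EPDR1 and RHOU were at least 1.54-fold to the negative side. WDR20 was at least 5.63-fold, with arrays also far apart (SD 6.58), and PTPN4 lay at −2.48 with an SD of 2.82. On the positive side H4C3 met the rule at 1.36 and C5AR1 was at least 1.62-fold. The promyelocyte list had 2 of 7 expressed members above 0 (median −0.27, percentile 16.1, with an RNA dim for 2 of the 7), and the cholesterol list 1 of 5 (median −0.50, percentile 6.61). At 12 h the promyelocyte list had 5 of 7 above 0 (median 0.13, percentile 87.0), and at 24 h it lay at percentile 39.2. In all 72 probes met the rule (35 positive, 37 negative), against 2 with the swapped sign turned. With all 4 intensities above 800 the count was 37.

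Between time points, 2 genes met the size rule at all 4, CCND3 on the positive side and NR1D2 on the negative side. CXCL8, FLJ20060 and C1orf56 did so at 3 time points on the positive side, and ICE1, VDAC3, MEST, NGLY1 and HSP90AB1 at 3 on the negative side. NGLY1 at 48 h and HSP90AB1 at 12 h had no value on both arrays, so the rule could not be applied there. The deposited value table has them at −1.89 and −1.11. The 24 and 48 h samples shared 14 positive probes where 2.21 would be expected and 7 negative ones where 1.26 would be, and the 6 and 48 h samples shared 10 negative ones where 1.07 would be. In the 6 pairs of time points, 0 probes met the rule on opposite sides. Across genes, which are not independent replicates, Pearson's r between time points ran from 0.25 (6 and 24 h) to 0.50 (24 and 48 h). Spearman's rho ran from 0.13 (6 and 24 h) to 0.48 (12 and 48 h), with 0.36 for 24 and 48 h. Over the 9860 probes of the value table with 4 values Pearson's r ran from 0.05 (6 and 24 h) to 0.29 (12 and 48 h). The study gives 102, 272, 461 and 659 changed probes at 6, 12, 24 and 48 h over whole arrays (2.12%, 4.31%, 7.29% and 9.82% of those expressed), beside 5.54%, 3.56%, 9.61% and 8.05% of expressed probes here. Here the stricter intensity condition for calls was applied to the changed probes, but not to the expressed probes they are divided by. The study's expressed probes may have been counted by another rule, so the percentages are not directly comparable.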

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

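The filter to both RNAs above background, the use of every probe of the value table, and the added 200 for the slope and the lists were chosen after the data were seen. Of 262 values of named gene means under an alternative, 152 kept their side and their standing at the threshold, 95 lost the call, 14 newly passed and 1 changed side. CCL3, CD83, NFKB1, NFKB2 and IDI1 had missed the threshold in the main fit, and were counted as kept where they missed it again. Without 48 h, where 0 probes passed, 5 values were counted as kept and 13 lost the call. Of 438 values of named genes at a single time with both arrays used, 358 moved by less than 1 SD between arrays and 80 by more. With 200 added 47 moved and 64 did not, and with loess 27 moved and 83 did not. No centring and the value table moved 3 each, but the first only shifts whole arrays and the second mostly equals the mean of the pair. The SD is each gene's own, so genes whose arrays lay far apart could hardly count as moved. Single arrays were not counted, because each lies within 1 SD of its pair's mean by construction. No slope had passed in the main fit, and 46 of 61 values again did not, while 15 newly passed. For list means 40 of 46 were the same, among them lists that were called in neither fit. Many spots were dim, and many calls had an RNA at background.

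Over the 4 time points the count of 15 became 0 with no intensity filter and 0 with every probe of the value table, 42 for probes expressed at all 4 times (38.1% positive against 66.7%), 2 with the first and 1 with the swapped arrays. It was 39 with a trended, robust prior, 30 with normexp and an offset of 50, 31 with 200 added, and 29 with both RNAs above background. Leaving out single times gave 0 (without 48 h) to 43 (without 6 h), with 3 without 24 h and 8 without 12 h, where each fit rests on fewer samples. No centring gave 20 (10 positive, 10 negative), the value table of the same probes 20 (7 and 13) and loess 10 (7 and 3), against 10 and 5. The trended prior gave 16 and 23, and 200 added gave 15 and 16. For the slope the count of 0 became 2 with loess, 1 with the value table of the same probes, 1 with the trended prior, 5 with 200 added, and 0 to 8 on leaving out single times (8 without 24 h, 5 without 12 h).

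The 1 list called became 0 for probes expressed at all 4 times and with the value table, same probes or every probe, where the chemokine list had too few members to be tested. It became 0 with the estimated correlation (adjusted p = 0.237) and with fry (adjusted p = 0.144), while under the other alternatives its adjusted p ran from 1.19e-08 to 1.44e-04. With the first arrays alone the promyelocyte mean came to 0.10, the G1/S mean to −0.0022 and the NFKB1 mean to −0.027. On leaving out single times the promyelocyte mean ran from −0.18 (without 6 h) to 0.072 (without 48 h), with 0.023 without 24 h.

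At 6 h the count of 44 became 6 at 2-fold, 17 with each array past the threshold, 513 with no filter, 28 with all 4 intensities above 800, 26 with loess, 86 with the value table of the same probes, 5618 with its every probe, 87 with the first and 107 with the swapped array, and 14 with 200 added. At 12 h the count of 36 became 110 at 1.5-fold, 12 with each array, 241 with no filter, 17 with all intensities above 800, 1766 with the whole value table, 62 and 55 with the first and swapped array, and 19 with both RNAs above background. Its 11 positive and 25 negative probes became 25 and 23 with the value table of the same probes, 12 and 14 with 200 added, and 13 and 17 with no centring. At 24 h the count of 81 became 205 at 1.5-fold, 304 with no filter, 39 with all intensities above 800, 1917 with the whole value table and 41 with 200 added. At 48 h the count of 72 became 204 at 1.5-fold, 263 with no filter, 37 with all intensities above 800 and 3386 with the whole value table. Except where fewer probes or samples were used or the fold was changed, the cause was not tested.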

Other observations

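The test of dye bias in the chemokine genes and the test of outlying spots at 12 h were chosen after the result was seen, as were the analyses of the value table and of probes above background.

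The deposited value table holds values at all 4 times for 9860 probes, also outside the scanner files. Over these, limma called 0 probes, with 1386 at an unadjusted p under 0.05 where 493 would be expected. The smallest adjusted p was 0.192. The genes named next had a small p, but were picked after the values were seen and not by rank alone. OMA1 (mean −2.18, SE 0.37) and PTPRE (1.33, SE 0.27) ranked above some of them. HMGCS1, of cholesterol synthesis, had log2 ratios of −1.43, −1.66, −1.75 and −1.30 at 6, 12, 24 and 48 h. Its 6 h value is close to that of the swapped array (−1.42), while the first array gave −0.22 and their mean was −0.82. HSP90AB1, a cytosolic chaperone, had a mean of −1.24 (SE 0.21). NGLY1 had a mean of −1.28 (SE 0.22). On the positive side were S100P, a calcium-binding protein, at 1.98 (SE 0.41), SAT1, which breaks down polyamines, at 1.14 (SE 0.20) and CD55, which shields cells from complement, at 1.02 (SE 0.21). None passed the adjusted threshold. Of 9 lists tested in this table with camera none passed. Their members were only probes named through the scanner files, 5 to 13 per list and 7 for cholesterol. They were set against all 9860 probes, most of them without a name, so this is not a test of whole lists. The smallest p was that of the cholesterol list, with a mean of −0.44 (adjusted p = 0.0967, and 0.556 with an estimated correlation), followed by the cell death regulators at 0.41 (adjusted p = 0.111) and the cytosolic heat shock proteins at −0.41 (adjusted p = 0.112).

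Among the probes with both RNAs above background at every time, 29 passed with limma (13 positive, 16 negative), 5 of them shared with the 15 of the report. IDI1 lay at −0.84 (SE 0.19, adjusted p = 0.0087), HSPH1 at −0.69 (SE 0.20), RNF135 at −0.93 (SE 0.20) and VDAC3, a channel of the outer mitochondrial membrane, at −0.81 (SE 0.21). PRIM1 and ORC3, which act in DNA replication, lay at −0.68 (SE 0.19) and −0.70 (SE 0.18). On the positive side were CD83 at 1.06 (SE 0.26), SPAG5 at 0.94 (SE 0.22), H4C3 at 0.85 (SE 0.20) and the mitotic motor KIFC1 at 0.77 (SE 0.20).

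The chemokine and NF-kappaB genes lay on the positive side at 24 and 48 h, in 11 of 14 member values with both arrays. The tables argue against dye bias of single spots, since the median dye part was 0.404 against a shared part of 1.88 on the log2 scale. Inflation by dim spots as the whole of the shift is also argued against. With 200 added to both intensities before loess the median over both times was 1.49, and 9 of 10 values still met the size rule. Dim spots may still have enlarged the sizes. With dim members at their bound the median at 24 h went from 2.18 to 1.71, while at 48 h it stayed at 1.59. Without CXCL8 the camera p of the list was 7.67e-05, so that gene alone did not carry the call, although with an estimated correlation the p was 0.0968. A shift of these genes with bufalin may explain the pattern, as a hypothesis. A difference between single cultures stays open, because no time point has a second culture, and so does the side on which bufalin stands.

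Over all expressed probes the paired arrays at 12 h were less alike than at other times. The median Cy3 background was 306 on the first array and 127 on the swapped one, and among probes with all intensities above 800 Pearson's r came to 0.439, above the lowest of the other pairs (0.212). Dim spots on a high background are thus a candidate explanation, though the pairs at 24 and 48 h were also more alike among bright probes (0.708 and 0.846). A few outlying spots are argued against by Spearman's rho, which was 0.0903 against 0.221 for the lowest other pair. After loess rho was 0.00641 at 12 h, over 929 probes, against 0.164 for the lowest other pair. Loess was run on ratios computed anew from the intensities. It therefore cannot show whether a dye effect that changes with intensity remains in the deposited ratios. No biological explanation was tested, since both arrays hold the same RNA.

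Giving the 4 time points other patterns of signs yields 8 patterns, too few for a share under 0.05. The real one, with 15 probes, was the 1 pattern with as many, and the highest of the others had 0.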
